A study of Homo sapiens with 4 samples.

How the data were processed

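Total RNA from primary human skeletal muscle cells was labelled with biotin and hybridised to Illumina BeadChips, per the labels' protocols. The series held 4 arrays on 1 chip: control and TSA-treated myoblasts and control and TSA-treated myotubes, with 1 array per group. Groups were taken from the sample titles. The dose and duration of TSA, the number of donors and the differentiation protocol are not given in the sources used here. No label says whether the 4 cultures came from the same cells.

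The authors deposited a table of non-normalized intensity values per probe, which per the file headers holds a signal and a detection p-value for each of the 4 arrays. The detection p-value deposited by the authors compares a probe with the array's negative controls. The intensities are linear and no background had been subtracted, as far as the lowest values (25.3 to 27.5) show. The software is not given in the sources used here. The authors also deposited log2 values of the same arrays. These differed by at most 0.00796 from log2 of quantile-normalized deposited signals, which settles their scale; their medians were 5.78 on each array, and they were used as an alternative. A table of scanner metrics was not used.

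The deposited intensities were corrected for background with limma's normal-exponential model, with the background estimated from the detection p-values and an offset of 16, then quantile normalized between arrays and taken to log2 (R 4.3.3, limma 3.58.1). Of 22184 probes, 19715 had 1 gene symbol, 0 had several and 2469 had none in the platform annotation given. Of these, 19695 matched a gene of the RefSeq table (GRCh38.p14) by gene number, and 0 symbols needed updating. Each of the 16546 genes was represented by the probe with the brightest mean over the 4 arrays, and 2272 genes had more than 1 probe. Over 491 genes with a second detected probe, the 2 probes' TSA differences in myoblasts correlated at r = 0.75 across genes, and 35 of 38 genes called by the brightest probe had the same sign by the other, and 16 of the 38 were also at least 2-fold by it. In myotubes the correlation was 0.26 over 515 genes. Probes can also pick up near-identical genes, such as MYH6 and MYH7, the DEFB103 copies, histone genes and HSPA1A and HSPA1B. Some genes were left out of all comparisons for reasons of privacy.

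A probe was called detected at a detection p-value under 0.01. Genes detected were 9218, 8798, 8786 and 8935 on the myoblast control, myoblast TSA, myotube control and myotube TSA arrays, 9810 on at least 1 array and 8004 on all 4. Median intensities were 57.7, 54.9, 54.5 and 52.3. Where 1 array of a pair did not detect a gene, its value was set to the higher of its own and the lowest detected value of that array, so the fold is a lower bound and is written as "at least". Genes detected on neither array were not compared. A gene was counted as higher or lower from a fold of 2. The difference of responses used the same floor and genes detected on at least 1 of the 4 arrays. Array pairs correlated at r = 0.979 in myoblasts, 0.996 in myotubes and 0.941 to 0.946 across states.

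With 1 array per group, no p-value is given for a comparison of 2 arrays. An additive limma model (state and treatment, empirical Bayes with an intensity trend, Benjamini-Hochberg adjustment) over the 4 arrays gave effects shared by both states or both treatments. It has 1 residual degree of freedom. The 28 gene lists were fixed before the data were examined, and a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This describes these arrays and is not a test. Lists with fewer than 3 compared genes got no percentile.

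Named genes were chosen by a rule fixed before the data were examined. For each pair of arrays it took the 10 largest differences per direction among genes detected on both, and the 5 largest lower bounds per direction among genes detected on 1. For the difference of responses it took the 8 largest per direction among genes detected on all 4 arrays, and for the limma fits the 5 smallest p-values per direction. It added the 2 to 4 members of each list with the largest differences and a fixed set of regulators. ACTA1 and HDAC10 of that set have no named probe here, and 1 item of it is not reported here. The report names part of the genes this rule gives. The 12 genes plotted by level were chosen among them after their values were seen, and so were CLK1, HSPD1, HSP90AA1, MYH2 and MYBPC2.

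Alternatives were median scaling, the authors' log2 values, no background correction, an offset of 50, detection at 0.05, no detection filter, detection on every array compared, and the mean of a gene's detected probes. For the limma fits, a robust prior without a trend was also tried. The steps were tested on simulated data for 8004 genes with an array noise of 0.135 (log2) and 200 changed genes. For TSA in myoblasts, the 2-fold rule recovered 100% of genes changed 4-fold and 50% of those changed 2-fold, with 0 false calls. The noise was taken from the myotube TSA differences and holds no difference between cultures. It is too small to pass the 2-fold rule, and a change of exactly 2-fold lies at the threshold. Both results of this rule therefore follow from the setting and tell nothing of false calls in the data. For a TSA effect shared by both states, limma recovered 100% at each size, with 10 false calls. The same change was planted in both states, so the only residual was that noise. In the data the residual is the difference between the responses of the 2 states, so these figures do not carry over to it. Of 200 unchanged lists of genes with independent noise, 4.50% lay outside the central range. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.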

Results

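Gene expression was measured in primary human skeletal muscle cells in 2 states, undifferentiated myoblasts and the multinucleated myotubes that they form when they differentiate. Each state was profiled without treatment and after treatment with trichostatin A (TSA), an inhibitor of histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The 4 groups held 1 array each, so there were no replicates: differences between a pair of arrays describe those arrays, have no test and carry no error. A gene was counted as higher or lower when it differed at least 2-fold and was detected on at least 1 of the arrays compared. Of 22184 probes, 10789 were detected on the myoblast control array, 10176 on the myoblast TSA array, 10236 on the myotube control array and 10444 on the myotube TSA array. The number of arrays limits the precision of every value below.

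The first comparison asked which genes differ with TSA in undifferentiated myoblasts. Genes of the contractile apparatus were among the largest differences toward higher values on the TSA array, and genes of mitosis among those toward lower ones. MYH7, the slow myosin heavy chain, was 5.32-fold higher, the fast troponin TNNC2 4.50-fold higher, and the myosin light chains MYL1 and MYL11 4.24-fold and 3.84-fold higher. CKM, the muscle creatine kinase, was 4.27-fold higher, EEF1A2, a translation elongation factor of muscle and neurons, 4.65-fold higher, and TMOD1, which caps actin filaments, 3.89-fold higher. The calcium channel subunit CACNG1 was 3.87-fold higher and CASQ2, a calcium-binding protein of the sarcoplasmic reticulum, 3.57-fold higher. DEFB103A, a defensin, was 4.07-fold higher, though its probe may not separate it from its near-identical copy. Among genes detected only with TSA, TSPAN7 was at least 2.78-fold higher, the troponin TNNI2 at least 2.45-fold, NEURL2 at least 2.22-fold and SLN, a regulator of the calcium pump, at least 2.07-fold. MYH6 was at least 2.02-fold higher, but it closely resembles MYH7.

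The largest differences in the other direction were in genes of the mitotic spindle and centromere. CENPF was 6.30-fold lower with TSA in myoblasts, DLGAP5 5.62-fold, ASPM 5.36-fold, the spindle motors KIF11 and KIF14 5.28-fold and 4.80-fold, and the centromere motor CENPE 4.84-fold. HMMR was 4.79-fold lower, CEP55, which acts in the last step of cell division, 4.47-fold, the kinase ROCK2 4.38-fold and the DNA polymerase POLQ 4.36-fold. Among genes detected only without TSA, the cytokinesis gene ECT2 was at least 4.07-fold lower, CCDC18 at least 3.12-fold, the DNA repair gene MRE11 at least 3.01-fold, CNTRL at least 2.997-fold and WDR35 at least 2.88-fold. In all, 147 genes were higher and 589 lower among 9406 compared, so 80.0% of the differences were toward lower values. Quantile normalization left the median of all compared genes at 0.12 (log2). Median scaling put it at 0 and gave 102 higher and 839 lower.

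Gene lists fixed before the data were examined are described by the median log2 difference of their members and its percentile among 10000 random lists matched on mean expression. Of 32 genes of the sarcomere and contractile apparatus compared, 20 were at least 2-fold higher with TSA in myoblasts and 0 lower. Their median was 1.30, at percentile 100, and MYH3, the embryonic myosin, was 3.37-fold higher. Of 18 genes of muscle metabolism and calcium handling, 8 were higher and 0 lower, with a median of 0.87 at percentile 100. HRC, which binds calcium in the sarcoplasmic reticulum, was 3.53-fold higher. The list of muscle membrane, acetylcholine receptor and fusion genes had a median of 0.49, also at percentile 100. With no detection filter that median was 0.294, inside the main upper limit of 0.300, which was not drawn again. Of its members, DTNA was 2.65-fold higher, CAV3 2.04-fold higher and CKAP5 2.91-fold lower. Of 63 genes of the cell cycle, DNA replication and mitosis, 15 were at least 2-fold lower, 0 were higher and 57 lay below 0, and their median was -0.57, at percentile 0. TOP2A was 3.90-fold lower, whereas TYMS, an enzyme of thymidylate synthesis, was 1.31-fold lower.

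The TGF-beta, activin and BMP list had a median of -0.19, at percentile 0.31, with BMPR2 2.24-fold lower, GREM1 2.14-fold lower and SMAD5 2.02-fold lower. All 31 oxidative phosphorylation genes compared lay above 0, with a median of 0.36 at percentile 100, although 2 of them, COX7A1 and NDUFC2, reached 2-fold (2.37-fold and 2.01-fold higher). The other lists with a median lay inside the central 95% of random lists. Of 27 lists with enough members, 4 lay above that range and 2 below it, against 1.35 expected outside it for lists of random genes. Genes of a list can vary together between cultures, so an excess over that number does not by itself show a response. Random lists were also not matched on genomic span, along which the differences in myoblasts fell (rho = -0.29 across genes). The median was 0.25 in the shortest of 3 equal groups by span and -0.06 in the longest, so list percentiles may partly reflect gene length.

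**Figure D1:**
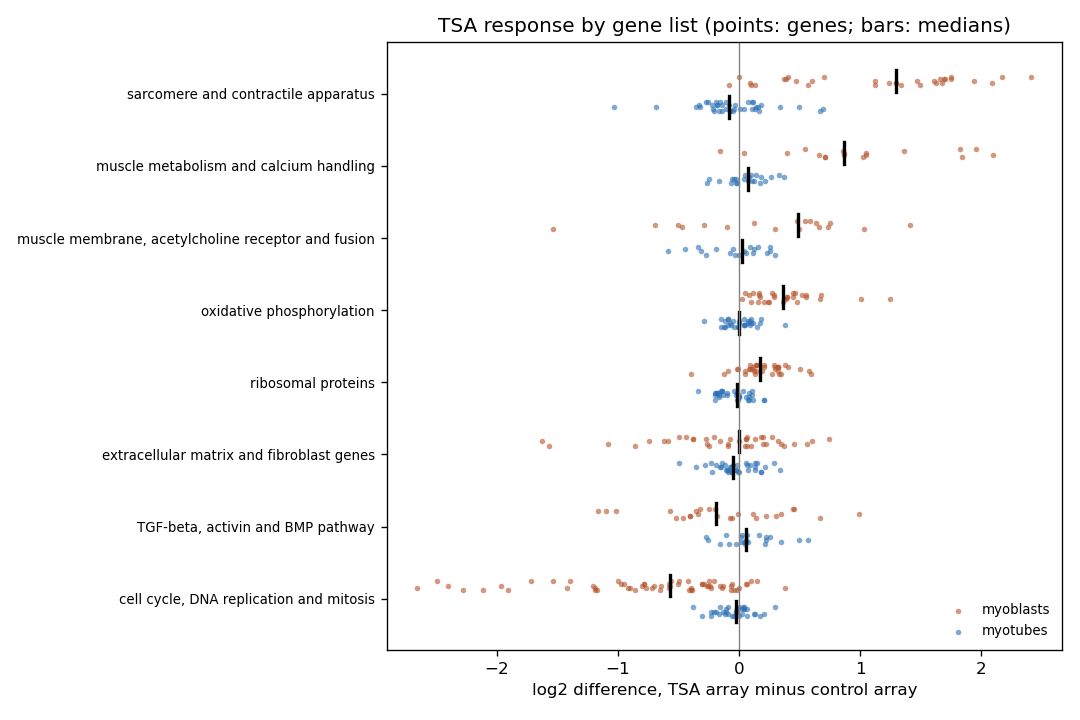
Log2 difference between the TSA and control arrays (horizontal axis) for the members of 8 gene lists, in myoblasts and in myotubes, with a point per gene and a black bar at each median. The sarcomere list has a median of 1.30 in myoblasts and -0.08 in myotubes, and the cell cycle list -0.57 and -0.02.

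Of the regulators named whatever their values, MYOG, the transcription factor of muscle differentiation, was 2.65-fold higher with TSA in myoblasts and MYOD1 1.63-fold higher, while MEF2C was 1.14-fold lower. The myogenic transcription factor list as a whole had a median of 0.03, which was -0.07 with median scaling. Its members went both ways, with TCF12 2.24-fold lower and ID1, an inhibitor of myogenic factors, 1.57-fold lower. The cell cycle inhibitors CDKN1C and CDKN1A were 2.24-fold and 1.26-fold higher, GADD45G 3.09-fold higher and CDK6 2.10-fold lower. CCND1 was 1.05-fold lower, a direction that turned with median scaling. The list of inhibitors, cyclins D and pocket proteins had a median of 0.25. MKI67, a marker of proliferation, was 1.81-fold lower. FST, which binds myostatin, was 1.59-fold higher and MSTN, myostatin itself, 1.70-fold lower. The ubiquitin ligases of muscle atrophy FBXO32 and TRIM63 were 2.04-fold and 1.54-fold higher, and the atrophy list had a median of 0.08. UTRN was 1.12-fold lower, and DMD was detected on neither myoblast array.

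Among the histone deacetylases themselves, HDAC2 was 1.85-fold lower with TSA in myoblasts and HDAC11 1.56-fold higher. HDAC1 was 1.02-fold higher, HDAC3 1.16-fold, HDAC4 1.20-fold, and HDAC6 was 1.06-fold lower. HDAC8 was 1.10-fold higher, which turned with median scaling. HDAC9 was detected in myotubes and on neither myoblast array, HDAC5 and HDAC7 on no array. SIRT2, a deacetylase of the sirtuin class, which TSA does not inhibit, was 2.65-fold higher. The list of deacetylases had a median of 0.24, which was 0.07 with median scaling. Acetyltransferases, corepressors and Polycomb genes had a median of 0.01, or -0.13 with median scaling, and SUZ12 was 2.87-fold lower.

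Markers of other cell types were examined the same way. Extracellular matrix and fibroblast genes had a median of 0.00 with TSA in myoblasts, while POSTN was 3.09-fold lower and FAP 2.96-fold lower. Smooth muscle genes had a median of 0.12, or -0.02 with median scaling, with LPP 2.53-fold lower and DES 2.03-fold higher. Adipocyte genes had a median of 0.34, with FASN 2.19-fold higher. That median was 0.11 with no detection filter and 0.46 among genes detected on both arrays. Endothelial genes had a median of 0.21 over 4 members, or -0.03 over those detected on both arrays. Of 14 blood cell genes on the array, 2 could be compared. Of 26 germline and epithelial genes on the array, 3 were detected in myoblasts, all keratins, with a median of 0.22.

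The second comparison asked the same of differentiated myotubes. Few genes differed: of 9094 compared, 1 was at least 2-fold higher with TSA and 1 at least 2-fold lower. PPP3R1, the regulatory subunit of calcineurin, was 2.35-fold higher and TTN, the giant sarcomere protein titin, 2.04-fold lower, but the 3 probes for TTN ranged from -1.03 to -0.08 (log2). The central 95% of genes lay between -0.39 and 0.38 (log2), against -1.30 to 0.84 in myoblasts. The next largest differences were under 2-fold. The nuclear import factor IPO7 was 1.95-fold higher, NPAS1 1.83-fold, TMSB15A 1.83-fold, BEST2 1.76-fold, SCG5 1.71-fold, MUC1 1.70-fold, SLC22A17 1.67-fold, the clock gene PER2 1.65-fold and MOGS 1.63-fold. LIMS1 was 1.92-fold lower, GNB4 1.81-fold, FRMD3 1.80-fold, the microtubule protein MAP4 1.78-fold, RRBP1 1.77-fold, TGFBRAP1 1.76-fold, CUEDC1 1.76-fold and UBE2H 1.75-fold. RASAL2 was 1.72-fold lower by its brightest probe, yet its 2 probes went opposite ways, at -0.78 and 0.55 (log2). With a single array detecting the gene, LTBP4 was at least 1.66-fold higher, CYFIP2 at least 1.61-fold, METRN at least 1.59-fold, UTP23 at least 1.67-fold lower and UHMK1 at least 1.63-fold lower.

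**Figure D2:**
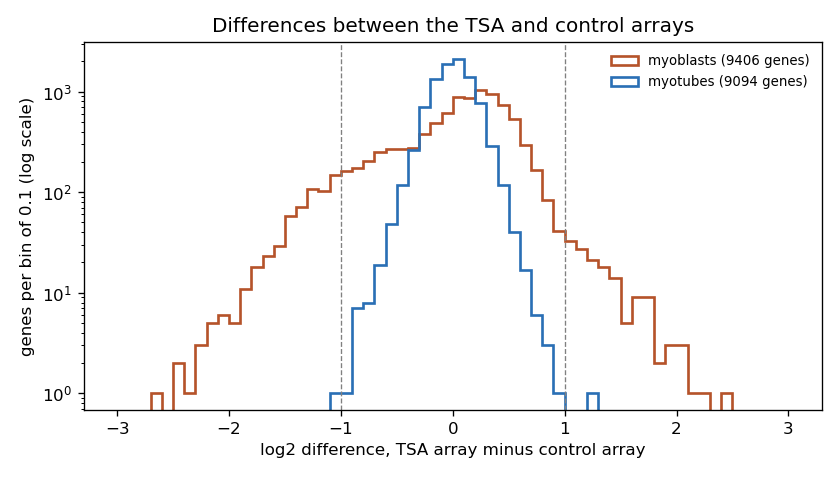
Number of genes (vertical axis, log scale) by log2 difference between the TSA and control arrays (horizontal axis, bins of 0.1), for 9406 genes in myoblasts and 9094 in myotubes. Dashed lines mark 2-fold; 736 genes lie at or beyond them in myoblasts and 2 in myotubes.

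Of the muscle genes higher with TSA in myoblasts, none of the sarcomere list was 2-fold higher in myotubes, but some went the same way: MYH2 was 3.04-fold higher in myoblasts and 1.59-fold higher in myotubes, and MYBPC2 differed by 1.34 and 0.49 (log2). In myotubes MYH3 was 1.08-fold lower, CKM 1.02-fold lower (a direction that turned with median scaling), MYOG 1.09-fold higher and CDKN1C 1.02-fold lower. The sarcomere list had a median of -0.08 over 40 genes, at percentile 0.25, or -0.05 with median scaling, inside the central range of the main setting. The cell cycle list had a median of -0.02 over the 35 genes detected. FBXO32 was 1.29-fold lower, MSTN 1.17-fold higher, DMD 1.503-fold lower, HDAC9 1.43-fold lower and HDAC1 1.23-fold higher. Of 26 lists, 3 lay above the central range and 4 below it, against 1.30 expected for lists of random genes. Those above were neuronal genes, with a median of 0.12, cholesterol and fatty acid synthesis, 0.15, and heat shock proteins, 0.09. Besides the sarcomere list, those below were smooth muscle genes, -0.13, interferon-stimulated genes, -0.08, and housekeeping genes, -0.10. Each of these medians is a difference of under 1.5-fold. Some moved inside the main central range, which was not drawn again, under an alternative. The heat shock median was 0.046 with median scaling, and the smooth muscle median -0.106 at an offset of 50. With no detection filter the neuronal median was 0.049 and the interferon median -0.061. The cholesterol and housekeeping medians stayed outside that range under each alternative.

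The third comparison set the response of myotubes against that of myoblasts, as the difference of the 2 log2 differences. It was not tested. It was at least 2-fold in the positive direction for 561 genes and in the negative one for 164, of 9810. Only 2 genes differed 2-fold with TSA in myotubes, so these counts mostly reflect differences in myoblasts. Median scaling gave 756 and 119, the authors' values 383 and 101, and detection on all 4 arrays 489 and 145. Mitotic genes were among the largest in the first direction: CENPE differed by 2.40 (log2), KIF20B by 2.26, HMMR by 2.24, TOP2A by 2.17 and ANLN by 2.08, and so were LUC7L3, which differed by 2.30, NKTR by 2.08 and PNISR by 2.08. Contractile genes led the other: TNNC2 differed by -2.36, MYH7 by -2.25, MYL1 by -2.19, CKM by -2.12, EEF1A2 by -2.02, MYL11 by -2.02, TMOD1 by -1.99 and XIRP1 by -1.95. The sarcomere list had a median of -0.96, at percentile 0, and the cell cycle list 0.49, at percentile 100. Many mitotic genes were near or below detection in myotubes, which limits how far they could be lower there. Across the 8004 genes detected on all 4 arrays, the TSA responses of the 2 states correlated weakly (r = 0.15, rho = 0.14, across genes, which are not independent replicates).

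**Figure D3:**
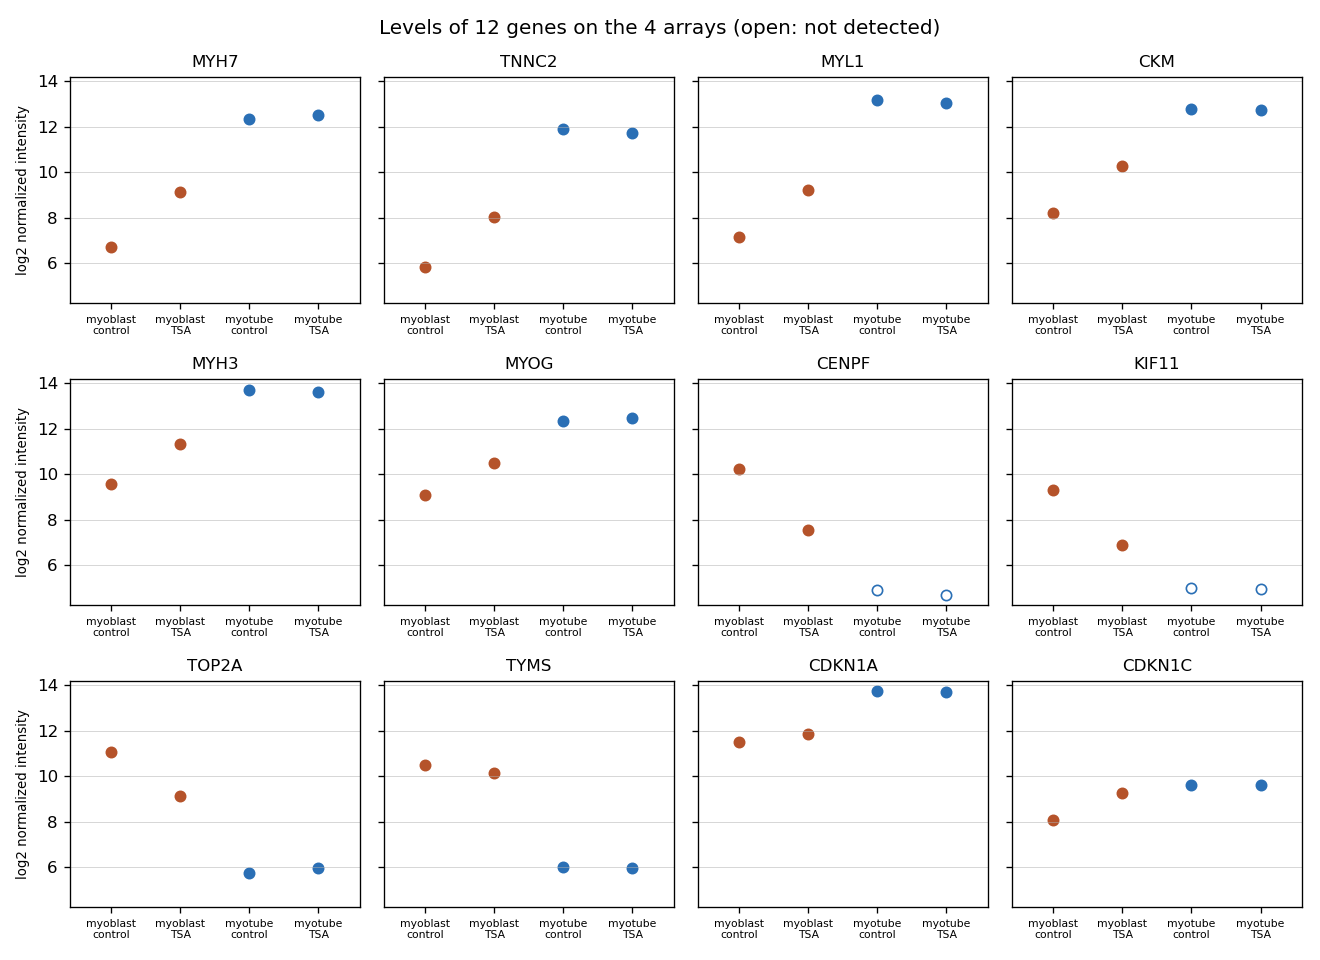
Log2 normalized intensity (vertical axis) of 12 genes on the myoblast control, myoblast TSA, myotube control and myotube TSA arrays, with a point per array and open points where the gene was not detected. MYH7 is 5.32-fold higher with TSA in myoblasts and 50.02-fold higher in control myotubes than in control myoblasts.

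The fourth comparison set control myotubes against control myoblasts, the difference between differentiated and undifferentiated cells. Contractile and calcium handling genes were higher in myotubes: TNNC2 66.9-fold, MYL1 65.3-fold, MYH7 50.02-fold, CASQ2 41.1-fold, MYOT 40.9-fold, NEB 39.1-fold, TNNT3 36.3-fold, TMOD1 32.1-fold and MYOM1 26.4-fold. The fatty acid transporter CD36 was 31.6-fold higher. SLN was at least 217.7-fold higher, MYBPC1 at least 65.5-fold, ATP1B4 at least 54.1-fold, TMEM182 at least 40.0-fold and BCAS1 at least 31.9-fold. Cell division genes were lower in myotubes: TOP2A 40.0-fold, the mitotic activator CDC20 36.6-fold, NUSAP1 35.1-fold, CEP55 28.6-fold, PRC1 27.1-fold, CCNA2 26.0-fold, TYMS 22.8-fold, CDK1 22.7-fold and BUB1 21.4-fold. TMSB15A was 19.7-fold lower. ID1 was at least 37.8-fold lower, ASPM at least 34.4-fold, CENPF at least 30.8-fold, KIF20A at least 29.5-fold and CCNB2 at least 27.9-fold.

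In total 766 genes were higher and 835 lower in control myotubes than in control myoblasts, of 9619. Median scaling gave 630 higher and 1053 lower. Of 40 sarcomere genes, 37 were at least 2-fold higher and 0 lower, with a median of 3.18, and of 22 genes of muscle metabolism and calcium handling 17 were higher, with a median of 2.56. Of 63 cell cycle genes, 58 were lower and 0 higher, with a median of -2.63. Among regulators, MYOG was 9.53-fold higher, MEF2C 13.8-fold higher, CDKN1A 4.65-fold higher, CCND1 3.49-fold lower, MYF5 13.1-fold lower and MYOD1 1.22-fold higher. FBXO32 and TRIM63 were 4.99-fold and 11.1-fold higher and MSTN 5.12-fold lower. Of 39 extracellular matrix and fibroblast genes, 19 were lower and 0 higher, with a median of -0.91, and THY1, a fibroblast surface marker, was 10.8-fold lower. Housekeeping genes, often used as references, had a median of -0.57, with ENO1 2.90-fold lower and PPIB 2.92-fold lower.

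The fifth comparison set TSA myotubes against TSA myoblasts and gave 1041 genes higher and 889 lower of 9485. The sarcomere list had a median of 2.41, with 31 of 40 genes higher, and the cell cycle list -2.13, with 55 of 62 genes lower. NEB, SLN, CD36, TMEM182 and MYL1 were again among the genes with the largest positive differences, and CDC20, TYMS, NUSAP1, PRC1 and CCNA2 among those with the largest negative ones. CDC20 was 19.95-fold lower and TYMS 17.7-fold lower, while AXL, a receptor kinase, was 12.1-fold lower and ID3 11.3-fold lower. MYBPC1 was at least 55.6-fold higher, MYOT at least 30.8-fold and MUSTN1 at least 10.9-fold. Of the 766 genes higher in control myotubes, 508 were also higher in TSA myotubes, and of the 835 lower ones 624 were also lower. No gene was called in opposite directions. Independent lists of these sizes would share 85.7 and 79.8.

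Genes that were higher with TSA in myoblasts overlapped with those higher in control myotubes: 126 of 147 were in both, and 1 was lower in control myotubes. Of the 589 genes lower with TSA, 120 were lower and 22 higher in control myotubes. Independent lists would share 12.1 genes in the higher direction and 52.8 in the lower one. Both comparisons use the same myoblast control array, so part of the excess may come from its chance values. With no effect simulated at an array noise of 0.135 (log2), the covariance of the 2 differences was 0.018 against 0.160 observed across genes. That simulated covariance follows from the noise put in, which was taken from the myotube pair and holds no difference between cultures. It therefore does not show how much of the observed covariance comes from the shared array. The simulated overlap was 0 in each direction, but noise of that size is too small to pass the 2-fold rule, so this tells nothing of the excess. With the mean of the control and TSA arrays taken for each state, 111 of the 147 genes were at least 2-fold higher in myotubes and 6 at least 2-fold lower. Of the 589 genes, 74 were then at least 2-fold lower and 84 at least 2-fold higher. Across genes, the covariance with this mean difference was 0.012 (r = 0.026, rho = -0.064). The mean also holds the TSA myoblast array with the opposite sign, which lowers the covariance where TSA has an effect. In the higher direction, 111 genes against 6 argue against chance values of the control array as the whole of the overlap. In the lower direction, with 74 against 84, how far the 2 differences share an effect stayed open.

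An additive limma model over the 4 arrays, with state and treatment as terms, was fitted to find effects shared across the other factor. It leaves 1 residual degree of freedom per gene, and limma's prior took over that spread entirely, so its adjusted p-values rest on the spread across genes. Limma called 18 genes higher and 29 lower with TSA in both states together at an adjusted p under 0.05, of 9810, and 880 at an unadjusted p under 0.05. MYL11 had a fitted log2 effect of 0.93 (SE 0.17), MYH7 of 1.28 (SE 0.25), CKM of 1.04 (SE 0.22), CENPF of -1.43 (SE 0.28) and FAM200A of -1.09 (SE 0.24). These calls do not show a shared response: 39 of the 47 genes had responses at least 2-fold apart between the states, 0 were 2-fold in both, and 36 had the same sign in both. Median scaling gave 0 calls, and no detection filter 2. For state, limma called 1575 genes higher and 1643 lower in myotubes, led by SLN, with a fitted effect of 7.26 (SE 0.29), and ID1, with -5.48 (SE 0.29). Median scaling gave 929 higher and 1440 lower. Of these 3218 genes, 3190 had the same sign with and without TSA and 1132 were at least 2-fold in both.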

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

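The tests of explanations in this part were written before their results were seen, except that the tests on the 11 genes detected on both myoblast arrays and with limits for undetected genes, and the intervals from added array noise, were chosen afterwards. The sarcomere list stood out because its median went opposite ways with TSA in the 2 states, 1.30 (log2) in myoblasts and -0.0793 in myotubes, each outside the central range of random lists. With median scaling the myotube median was -0.0461, inside the main central range (-0.0525 to 0.0660), which was not drawn again for that scaling, so its place outside the range was not shown for that scaling. The difference was not tested, since each state has 1 array pair, and the shift in myotubes is small.

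The list's median in myoblasts stayed at 1.07 or more under 5 scalings, which argues against these choices as the explanation for the higher muscle genes. Only median scaling among them replaced quantile normalization. An admixture of cells like those on the myotube arrays stays open. It would bring all their abundant transcripts in 1 proportion. The test took 24 genes at least 16-fold higher in myotubes by the mean of the control and TSA arrays of each state. Of these, 33.3% gave an implied share within 2-fold of the median share of 1.86% (20.8 to 45.8% with array noise added). This met the bound of under 50% set beforehand against an admixture, but that bound took the measured level of undetected genes as exact, and only 11 of the 24 genes were detected on both myoblast arrays. Among the 11 genes, 54.5% lay within 2-fold of their median of 5.22% (36.4 to 72.7% with noise added). In another form of the test, the last tried, an undetected level was allowed anywhere from 0 to the lowest detected one, with noise added. Shares from 2.08 to 2.27% then lay within 2-fold of the limits of 91.7% of the 24 genes, above the 90% an admixture needs, so this form did not exclude it. But the myoblast mean that chose the 24 genes includes the TSA array, so their choice depended on the response. It left out CKM and MYH3, for example, 23.85-fold and 17.55-fold higher in control myotubes than in control myoblasts. With TSA in myoblasts they were 4.27-fold and 3.37-fold higher. The percentages of the 24 genes therefore decide neither for nor against an admixture. With no 2-fold allowance, 62.5% of the genes at most could have the same share, and NEB (at most 1.19%) and SLN (at most 1.14%) lay below MYH7 (at least 5.68%), which speaks against a single share without deciding, since the noise is that of probes and not of cultures. A fraction of cells at an earlier stage of differentiation, a higher level in many cells, an effect of TSA itself and a difference between cultures, with 1 per group, stay open too.

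Probes without a gene name, which the comparisons leave out, also held differences. With TSA in myoblasts, 59 of the 778 such probes detected on both arrays were at least 2-fold apart, 12 higher and 47 lower, and in myotubes 0 of 799.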

How the results depend on the processing

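With 1 array per group, no replicate could be left out, and no paired analysis was possible within a state. Across the 2 states, the additive limma model pairs the TSA and control arrays by state. The trend with genomic span was the only alternative chosen after seeing the data. Total counts stayed within 1.5 times their main value under the other alternatives except as follows, and the cause was not tested unless given. With an offset of 50, which shrinks differences of dim genes by construction, 444 genes differed with TSA in myoblasts instead of 736, 417 in response instead of 725, and 0 with TSA in myotubes instead of 2. That last count was 1 with the authors' values, 1 without background correction, 1 with the mean of detected probes and 4 with no detection filter. For a TSA effect shared by both states, limma called 47 genes in the main setting, 0 with median scaling, 2 with no detection filter, 29 among genes detected on all arrays (16 higher and 13 lower) and 8 with a robust prior without a trend. It called 14 higher and 37 lower with the authors' values, and 14 and 39 with an offset of 50, against 18 and 29. By direction, counts also moved further: genes higher with TSA in myoblasts from 147 to 97 with the authors' values or no background correction and 84 at an offset of 50, lower ones from 589 to 360 at that offset, response differences from 561 and 164 to 328 and 89 there, the lower ones to 101 with the authors' values and 102 without background correction, and limma's higher state calls from 1575 to 929 with median scaling.

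All 444 genes at an offset of 50, and 681 of the 941 under median scaling, were among the 736 called in the main setting for TSA in myoblasts. After removing the trend with genomic span, 206 genes were higher and 341 lower, and 461 of the main calls remained. In named genes, 1116 values moved by less than the spread of a single probe, 292 moved by more, and 0 changed sign among those at least 2-fold. Of the fitted limma effects of named genes, 143 kept their direction and their side of the threshold, and 25 kept their direction but no longer passed it. Of the list medians, 926 moved from their main value by less than the standard deviation of random lists' medians, and 130 moved by more. With no detection filter, 2 medians outside the central range changed sign: neuronal genes in control myotubes against control myoblasts, from -0.37 to 0.0085, and the insulin-like growth factor pathway in TSA myotubes against TSA myoblasts, from -0.74 to 0.063. Signal over background limits what can be said of genes near detection.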

Other observations

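Other gene groups were compared between the states. Of 21 genes of cholesterol and fatty acid synthesis, 15 were at least 2-fold higher in control myotubes than in control myoblasts and 0 lower, with a median of 1.14 (log2) at percentile 100. HMGCS1, an early enzyme of the mevalonate pathway, was 6.13-fold higher, FDPS 4.59-fold and IDI1 4.07-fold. Of 24 interferon-stimulated genes, 11 were higher and 1 lower, with a median of 0.87 at percentile 100, led by MX1 at 20.6-fold, ISG15 at 11.3-fold and IFIT1 at 6.64-fold. Of 5 metallothioneins, 2 were lower and 0 higher, with a median of -0.89 at percentile 0.675, and MT1G was 6.08-fold lower. Oxidative phosphorylation had a median of 0.35 at percentile 99.9, with 2 of 32 genes higher, and its muscle isoform gene COX7A1 was 7.40-fold higher. In the insulin-like growth factor pathway, with a median of -0.39 at percentile 3.71, inside the central range, IGFBP5 was 6.53-fold higher and IGFBP4 4.80-fold lower. Its median was -0.55 with median scaling, below the main lower limit of -0.435, and -0.16 with no detection filter. Inflammatory mediators had a median of -0.34, below the central range, with 3 of 18 genes lower and CXCL8 2.78-fold lower. With no detection filter that median was -0.19, inside the main lower limit of -0.296. Histone genes had a median of 0.35, inside the central range at percentile 96.8 (0.06 with no detection filter), with H2BC21 8.16-fold higher and H2AZ1 3.80-fold lower, and ribosomal proteins 0.03 at percentile 60.2.

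With TSA in myoblasts, chaperone genes went both ways around a median of 0.16. The small heat shock genes HSPB8, HSPB3 and HSPB2 were 2.63-fold, 2.60-fold and 2.14-fold higher, and HSP90B1, HSPD1 and HSP90AA1 2.12-fold, 2.11-fold and 2.10-fold lower. Medians were 0.26 for cholesterol and fatty acid synthesis, 0.29 for interferon-stimulated genes, 0.20 for metallothioneins, 0.21 for histone genes, 0.17 for ribosomal proteins, 0.20 for neuronal genes, 0.23 for the insulin-like growth factor pathway, 0.25 for apoptosis genes, 0.04 for inflammatory mediators and 0.00 for housekeeping genes, each inside the central range of random lists. With median scaling the inflammatory median was -0.07, that of histone genes 0.02 and that of metallothioneins 0.01. The ribosomal median was then 0.33, above the main upper limit of 0.189, and the range was not drawn again. Among genes detected on both arrays, the interferon and apoptosis medians were 0.375 and 0.382, above their main limits of 0.334 and 0.341. BIRC2, an inhibitor of apoptosis, was 3.70-fold lower. LUC7L3 was 3.58-fold lower, NKTR 3.68-fold, PNISR 3.33-fold and CLK1 2.58-fold, and each was higher with TSA in myotubes by 1.15-fold to 1.38-fold. These 4 genes have roles in splicing and were picked after their values were seen, and splicing genes as a group were not examined.

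The tests of a trend with gene length as the whole cause, of a low range and of array noise alone were chosen only after the result was seen. More genes were lower than higher with TSA in myoblasts. At least 80.0% of the called genes were lower under each of 5 scalings. Only median scaling among them replaced quantile normalization, and it gave 89.2% lower. The pattern thus held under both methods. Each sets the arrays to a common level, so a shift shared by most genes could not be seen. For fewer dividing cells, the test took genes whose state means differed by under 0.5 (log2). Of their calls, 94.4% were lower (exact 95% interval 90.6 to 97.0), which met the bound set against that cause. But the myoblast mean includes the TSA array, so the choice of genes depended on the response counted. Of the 147 higher calls, 111 had a mean at least 2-fold higher in myotubes and fell outside the set. The test therefore does not decide whether fewer dividing cells account for the pattern. Gene length went with the pattern. In the shortest of 3 equal groups by genomic span, 42.7% of calls were lower (33.6 to 52.2), against 88.5% in the longest. Once the trend with span was removed, 62.3% remained lower (58.1 to 66.4). A trend of the average difference with length may thus be part of the cause and was not the whole of it. But 1.59% of genes were called lower in the shortest group, 5.93% in the middle and 11.3% in the longest. Removing an average trend leaves in place any growth of the spread with span. Whether length accounts for the whole pattern was therefore not decided.

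Few genes differed with TSA in myotubes. The TSA pair gave 120.6% of the state calls of the control pair, but it uses another myoblast array and quantile normalization evens the ranges, so this does not test the range of the myotube TSA array. With both myotube arrays set against the myoblast control array under median scaling, it gave 100.1% of the 2-fold differences of the myotube control array (bootstrap interval 97.9 to 102.3), which argues against a low range. Array noise alone is argued against by the correlation of 0.26 between probes of the same gene (bootstrap interval 0.147 to 0.369). A myotube array labelled TSA that had none was predicted to share no direction with myoblasts. Yet the 650 genes called in myoblasts and detected on all arrays had a signed mean of 0.0501 (log2) in myotubes, outside the central range of matched random sets (-0.018 to 0.0094), and 58.8% had the same sign. The random sets were matched on mean expression and not on genomic span. Differences fell with span in both states (rho = -0.29 in myoblasts and -0.077 in myotubes). A trend with span, or a technical factor common to both TSA arrays, such as handling, could give the same sign and was not tested. A weaker response of myotubes, or one at another time or dose, stays open.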
